A study of Drosophila melanogaster with 2 samples.

How the data were processed

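Chromatin immunoprecipitation followed by sequencing was performed on whole Drosophila melanogaster embryos aged 6 to 24 h, from a transgenic line that carries the transcription factor Fer3 fused to GFP at its C terminus. The precipitation used an antibody against GFP, and chromatin was sonicated to fragments of 200 to 800 bp, per the labels. The 2 samples are biological replicates 1 and 2 of 1 group, taken from separate biosamples of the same line, per the labels. The stage was taken from the sample source. A separate age field holds a number that is not a possible embryo age and was not used.

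For each replicate the authors deposited a narrowPeak list on the dm6 build. For the series they deposited a list made from both alignments pooled and a list thresholded by the irreproducible discovery rate (IDR), here called the reproducible list. Each replicate list was made against 1 shared control alignment, per the deposited file descriptions, and the reproducible list was derived from both replicate lists and the pooled list. The aligner, the peak caller and their settings are not given in the sources used here. The control's own values were not used here. Each peak carries the authors' signal value, a height on a scale that the sources do not define, and a deposited −log10 q. Both are the authors' numbers and were used only to describe, rank or filter peaks within a list, and the signal value also to correlate the replicates. The replicate lists and the pooled list each hold exactly 30000 peaks, so their length carries no information on how many sites each library could show.

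The lists hold no read counts, so the sequencing depth of each replicate is unknown. Shares of peaks are given with exact Clopper-Pearson 95% intervals, which cover counting error over peaks only. Peaks and genes are not biological replicates, and with 2 replicates of 1 group no comparison between conditions could be made. P-values compare sets of peaks, bases or genes within this experiment.

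Peak coordinates were compared with the Ensembl release 115 annotation (BDGP 6.54, dm6 coordinates) on chromosome arms 2L, 2R, 3L, 3R, 4, X and Y. Transposable elements were left out. No deposited peak runs past the end of an arm. A start is an annotated 5′ end of a protein-coding transcript, and a promoter is the bases within 500 bp of a start. Summits were taken from the deposited summit column. They lie outside the stated interval for 5 of the 5636 reproducible peaks and were used as given. Features were assigned in the order promoter, 5′ UTR, coding exon, 3′ UTR, other exon, intron and intergenic. Coordinates are given 1-based on dm6.

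Overlap of at least 1 bp between the replicate lists was compared with 1000 circular shifts of the other list along each chromosome (one-sided), and with 100 shifts in each alternative setting. Signal values of matched peaks, paired by the nearest summit within 100 bp, were correlated across peaks with 100000 permutations. Feature and chromosome shares were tested with exact binomial tests against shares of bases. Motifs were counted as present or absent on either strand in 101 bp windows around summits. They were compared with windows centred 500 bp to the left and right of the same summits by Fisher's exact test. The 10 E-box classes, a panel of 15 motifs and all 6-mers, each taken with its reverse complement, were each adjusted by the Benjamini-Hochberg method. A 6-mer was called at an adjusted p under 0.05 with an odds ratio of at least 1.5. Gene lists were compared with all other protein-coding genes by Fisher's exact test for a reproducible summit within 1 kb of any start. These p-values were adjusted over 17 lists. All binomial, Fisher and correlation tests are two-sided, and odds ratio intervals are 95% intervals on the log scale. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

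The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took Fer3, the gene with the nearest start to each of the 15 highest reproducible peaks, and up to 4 members of each list with the highest peaks. It also took up to 2 members without a peak for each list that passed the test. Lists cover bHLH factors, embryonic tissues, peptide hormones, Notch signalling, stress, ribosomal proteins, the proteasome, and chemosensory receptors. The last list takes every symbol of the odorant, gustatory and ionotropic receptor families. In all, 4 list members had no single match in the annotation and were left out. The peptide hormone list holds 1 symbol that the annotation assigns to a collagen-type gene, and it was kept as fixed.

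Alternatives changed the overlap rule, used the 5636 highest peaks of 1 replicate in place of the reproducible list, and took the 2818 highest of the reproducible peaks. They also changed the distances, window widths, backgrounds and gene links, and set the lists against 10000 random lists matched on gene length. Backgrounds and expected shares matched on GC content, and chromosome shares without Y, were added after seeing the data.

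The programs were tested on simulated data. With 40% of 30000 simulated peaks planted in a second list, the overlap above shifted lists recovered 40.1%. An E-box planted in 9.85% of 5636 real windows was recovered in 9.76%, with none of the 9 other classes called higher. The same planting led to the planted 6-mer and 4 others being called, and none was called without planting. The windows used lay 1000 bp from the summits, where GC content was near that of the flanks. The simulation thus does not show how many calls the low GC content of the summits can give. Of 200 simulated lists of 50 genes with double the base share of peaks, 99% passed at an unadjusted p under 0.05, as did 3.5% of unchanged lists. The 99% does not apply to the tissue, Notch and stress lists, which hold 9 to 24 genes and were tested with adjustment. The Notch pathway list (21 genes) and the stress list (19 genes) had a peak in 52.4% and 52.6% of genes. Other genes had one in 26.2% of cases in each comparison, yet neither list passed after adjustment.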

Results

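Fer3 is a basic helix-loop-helix (bHLH) transcription factor, a protein class that binds E-boxes, short DNA sites of the form CANNTG. Its chromatin occupancy was mapped in whole 6 to 24 h embryos with a GFP-tagged protein and an antibody against GFP, in 2 biological replicates. Each replicate list and the pooled list held 30000 peaks, and the reproducible list held 5636. All coordinates are on dm6. The depth behind each list is unknown, since the lists hold no read counts.

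The replicates shared their high peaks and differed in their low ones. Of the 1000 highest peaks of replicate 1, 998 overlapped a replicate 2 peak, and of the 1000 highest of replicate 2, 992 overlapped a replicate 1 peak. At ranks 20001 to 30000 the shares fell to 30.9% (95% interval 30.0 to 31.8) and 37.5% (36.5 to 38.4). Over the whole lists, 56.3% of replicate 1 peaks (55.7 to 56.9) and 59.2% of replicate 2 peaks (58.6 to 59.7) overlapped the other list. Shifted lists gave means of 13.8% and 14.4%, and none of 1000 shifts reached the observed share (one-sided permutation p = 0.001 in both directions, the smallest that 1000 shifts can give). Across 12293 peaks with matched summits, the authors' signal values ranked alike, with Spearman's rho = 0.813 and Pearson's r = 0.881 on log2 values (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). These correlations are across peaks, which are not independent replicates. Both lists were made against 1 shared control alignment, and neither the shifts nor the permutations account for agreement that comes from it. The shifts also do not keep peaks in promoters, so a preference for promoters in both lists could add to the excess over shifted lists.

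The reproducible list was made up of exactly the 5636 highest peaks of the pooled list by signal value. Replicate 1 held a peak at 96.8% of them (96.4 to 97.3) and replicate 2 at 98.6% (98.3 to 98.9). With at least 50% of both peaks required to overlap, the share in replicate 1 was 76.9%. All 5636 carried the same deposited −log10 q, 4.09, so this column does not rank them. In the full lists, a deposited q of at most 0.05 was reached by 29.7% of replicate 1 peaks, 57.5% of replicate 2 peaks and 44.5% of pooled peaks.

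**Figure D1:**
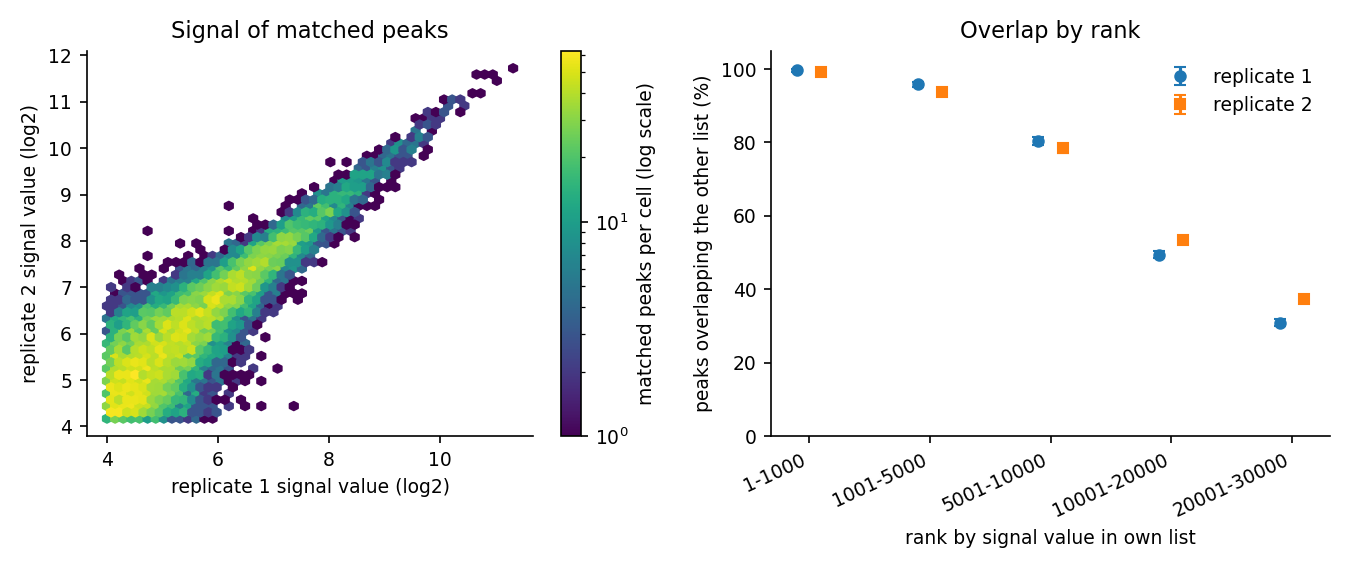
Left, log2 signal value of each replicate 1 peak against that of the replicate 2 peak with the nearest summit within 100 bp, as a density of the 12293 matched peaks (rho = 0.813). Right, share of peaks (%) that overlap the other replicate's list, by rank in their own list, with exact 95% intervals; it falls from 99.8% to 30.9% for replicate 1 and from 99.2% to 37.5% for replicate 2.

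The first question was where in the genome the peaks of the tagged Fer3 lay. Promoters held 44.9% of reproducible summits (43.6 to 46.2, 2531 of 5636) but 11.2% of bases, a 4.02-fold excess. Coding exons held almost no summits, 9 of 5636 (0.160%) against 13.6% of bases, or 4.55% when bases are weighted to the GC content of the summits. The 3′ UTRs held 1.08% of summits against 4.40% of bases, or 7.45% when weighted, and intergenic sequence 13.4% against 29.0%. Introns held 2148 summits, 38.1% against 39.5% of bases (exact binomial test, adjusted p = 0.0366). The 5′ UTRs held 0.515% against 0.771% (exact binomial test, adjusted p = 0.0366), and other exons, at 1.83% against 1.61%, did not differ past the threshold. For promoters and coding exons the binomial p was too small for the software to represent. The intergenic deficit had an adjusted p of 1.17e-168 by the same exact test. With the highest peaks of replicate 1 alone, the intron and 5′ UTR calls were lost, at adjusted exact p of 0.0654 and 0.633. The 5′ UTR call was also lost in the 2818 highest peaks (adjusted exact p = 0.326) and with GC-weighted shares (0.542), chosen after seeing the data, with which other exons passed as higher (1.32-fold, 0.00709).

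High peaks lay in promoters more often than low ones. Of the 1409 highest reproducible peaks by signal value, 55.0% had summits in promoters (52.4 to 57.6), against 41.7% of the 1409 lowest (39.1 to 44.4). The odds ratio was 1.71 (1.47 to 1.98, Fisher's exact test, p = 2.20e-12, chosen after seeing the data). Across the arms, chromosome 4, which is largely heterochromatic, held 18 peaks, 13.4 per Mb against 41.0 per Mb over all arms (exact binomial test, adjusted p = 3.41e-08). Chromosome arm 2L held 44.6 per Mb (exact binomial test, adjusted p = 0.00729), a call lost when Y, which held no peak, was left out of the base (adjusted p = 0.127). The X held 43.3 per Mb (exact binomial test, adjusted p = 0.0983).

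**Figure D2:**
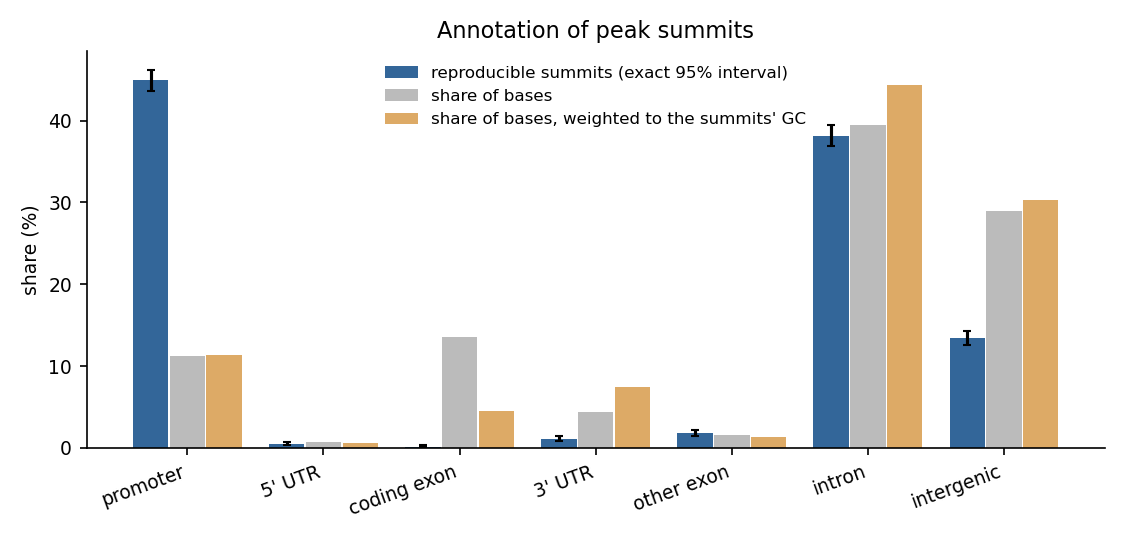
Share (%) of the 5636 reproducible summits in each annotation class (blue, exact 95% interval), beside the class's share of bases (grey) and its share of bases weighted to the GC content of the summit windows (orange). Promoters hold 44.9% of summits against 11.2% of bases, or 11.4% after weighting.

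The highest peaks marked promoters of genes with varied functions. The highest had its interval at 3L 19590410 to 19590821 and its summit 97 bp from a start of CG14100, with a signal value of 5902, followed by a peak in an intron of CG11050 (2L, 6612469 to 6612913, signal value 4996). Both mRpL41 (2R, summit 15217753, 136 bp from a start) and mRpS10 (3R, summit 15229538, 127 bp), which encode mitochondrial ribosomal proteins, were among the 6 highest. Others lay 32 bp from a start of the UDP-galactose transporter gene Ugalt (X, summit 2703884), 168 bp from a start of the glycolytic gene Gapdh2 (X, summit 15867977) and 485 bp from a start of the Polycomb group gene ph-p (X, summit 2137340). A peak in an intron of Trl, which encodes the GAGA factor, ranked 10 (3L, summit 14759512). The nearest starts to the remaining peaks were those of cbt (the peak lies in an intron of ush), CG4004 (the peak lies in an exon of the noncoding gene lncRNA:Vinr, 5075 bp away), CG13390, CG18549, PNPase, CenG1A and Tcs5. Of these 15 peaks, 11 had summits in promoters, 3 in introns and 1 in another exon.

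At the Fer3 locus itself (FBgn0037937, 3R, 11693410 to 11694311, minus strand), the reproducible list held 1 peak within 10 kb. It spans 11689933 to 11690296, with its summit at 11690115, 4196 bp from the Fer3 start and 64 bp from a start of CG6908, and ranked 4120 of 5636. Replicate 2 held a peak there with its summit at 11690081, rank 3072 of 30000 and a deposited −log10 q of 4.11. The replicate 1 peak there was lower in its list, with its summit at 11690230, rank 8482 and a deposited −log10 q of 1.38. The pooled list held 9 peaks within 10 kb of the gene, replicate 1 held 11 and replicate 2 held 9. A pooled peak lay 391 bp upstream of the Fer3 start, with its summit at 11694702 between genes. It had rank 13621 of 30000 and a deposited −log10 q of 1.27. Others of the 9 pooled peaks ranked higher, among them a peak in a coding exon of CG18765 at rank 7723. Replicate 2 held a peak with the same summit at rank 6758. In replicate 1 the nearest peak had its summit inside Fer3 at 11694144, 167 bp from the start. It had rank 15634 and a deposited −log10 q of 0.551. The labels describe an insertion that targets Fer3, and its coordinates are not given in the sources used here.

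Since Fer3 is a bHLH factor, E-boxes at its summits were compared with sequence 500 bp away. None of the 10 E-box classes was more frequent at summits, and 7 were less frequent. CACGTG was in 0.656% of summit windows and 1.47% of flanking windows (odds ratio 0.442, 0.309 to 0.632, Fisher's exact test, adjusted p = 3.84e-06). CACCTG was in 2.25% and 4.28% (odds ratio 0.516, 0.423 to 0.629, exact test, adjusted p = 6.26e-11), and CAGCTG in 3.55% and 5.27% (odds ratio 0.661, 0.562 to 0.779, adjusted p = 1.03e-06). CAGATG, CACATG, CAAGTG and CAACTG were also less frequent, with odds ratios of 0.609, 0.635, 0.721 and 0.731. CATATG had the highest odds ratio, 1.13 (0.956 to 1.34, exact test, adjusted p = 0.175), and CAAATG and CAATTG did not pass the test either, at 0.975 and 0.891. With windows of 100 bp either side, CATATG passed as higher, at 1.26 (exact test, adjusted p = 0.000339), and CAATTG as lower, at 0.838 (adjusted p = 0.00304). No relation of CATATG to peak height passed the test. It was in 4.40% of windows of the 1409 highest peaks and 3.69% of the 1409 lowest (Fisher's exact test, p = 0.390).

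Summits were A/T-rich, and the E-box result changed with the base composition of the background. GC content averaged 32.8% ± 9.29 (SD, n = 5636 windows) at summits and 43.3% ± 10.2 (SD, n = 11272) in the flanking windows. It averaged 30.1% in the 1409 highest peaks and 35.1% in the 1409 lowest (difference −5.07 percentage points, permutation p = 1e-05, the smallest that 100000 permutations can give, chosen after seeing the data). Against dinucleotide-shuffled summit windows, which keep composition, CAGCTG was more frequent (3.55% against 1.44%, odds ratio 2.52, 1.94 to 3.28, exact test, adjusted p = 4.63e-12), CAAATG and CATATG passed as higher at 1.22 and 1.43, and CACGTG alone passed as lower, at 0.585. Against genomic windows of the same GC content, added after seeing the data, only CAGCTG passed, at 1.55 (1.29 to 1.87, exact test, adjusted p = 6.05e-05), and no class was lower. These windows were not matched on distance to a start. Promoters held 44.9% of summits but 11.4% of bases weighted to the GC content of the summits. An excess over these windows therefore cannot be told apart from an effect of promoter location.

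**Figure D3:**
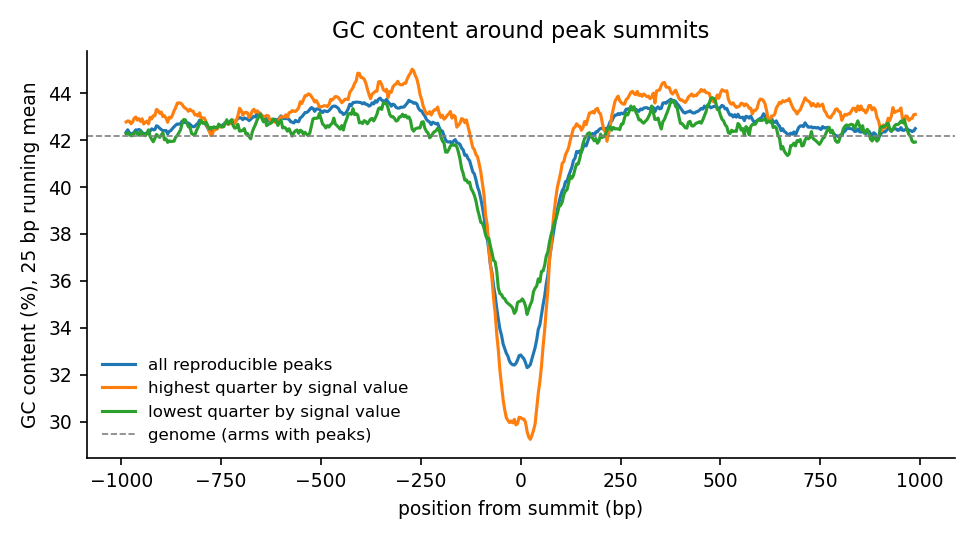
Mean GC content (%) by position from the summit (bp, 25 bp running mean) for all reproducible peaks and for the 1409 highest and 1409 lowest by signal value; the dashed line is the mean of the arms that hold peaks, 42.2%. At the summit the mean is 32.8% for all peaks, 30.2% for the highest and 35.1% for the lowest.

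**Figure D4:**
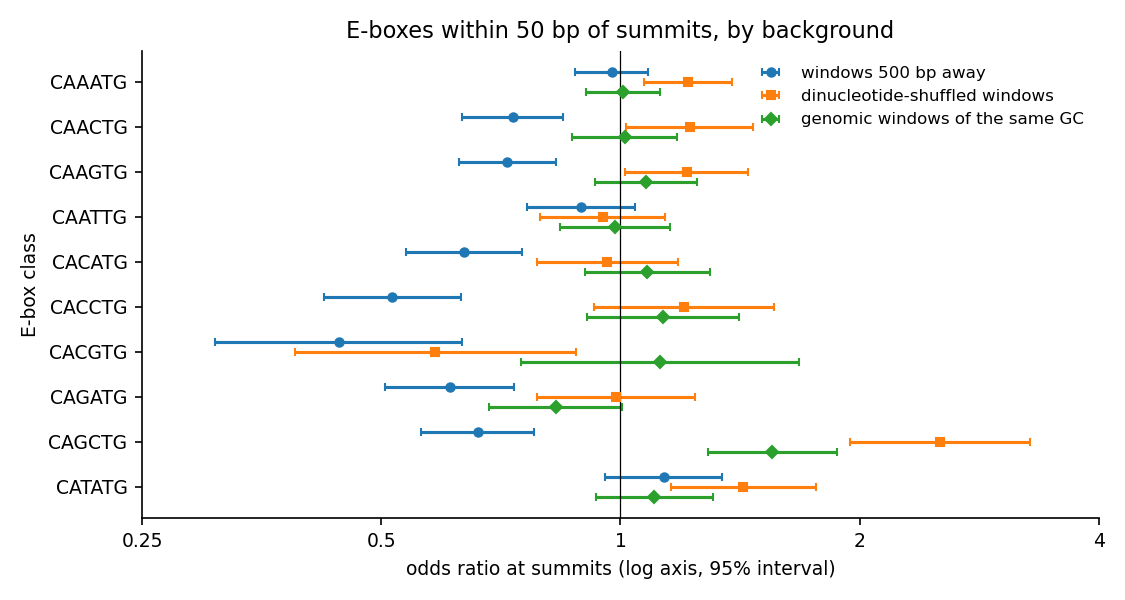
Odds ratio (log axis, 95% interval) of each E-box class within 50 bp of reproducible summits against 3 backgrounds. CAGCTG lies at 0.661 against windows 500 bp away, 2.52 against dinucleotide-shuffled windows and 1.55 against genomic windows of the same GC content.

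Motifs of promoter factors were the most enriched of the fixed panel. The site of DREF, a factor of housekeeping gene promoters (TATCGATA), was in 1.51% of summit windows and 0.231% of flanking windows (odds ratio 6.62, 4.26 to 10.3, Fisher's exact test, adjusted p = 3.71e-20). Motif 1, a core promoter element (GGTCACACT), was in 0.532% and 0.115% (odds ratio 4.63, 2.42 to 8.89, exact test, adjusted p = 3.64e-06). The DREF odds ratio was 10.4 (5.97 to 18.2) at peaks within 500 bp of a start and 1.64 (0.678 to 3.96) at the other peaks. That of Motif 1 was 5.45 (2.63 to 11.3) and 2.00 (0.404 to 9.92), and it was 2.96 (1.65 to 5.30) with the highest peaks of replicate 1 alone. The TATA, forkhead and GATA patterns, which are rich in A and T, were higher at 2.44, 1.92 and 1.58. GAGA, the N-box and the Grainyhead site were lower at 0.603, 0.715 and 0.296, and the other 7 motifs did not pass the test. At peaks within 500 bp of a start, Zelda passed as lower (0.637, 0.457 to 0.888). The Grainyhead call, from 4 summit windows, was lost with either replicate alone (0.521 and 0.600), the GAGA call with windows of 100 bp either side (0.995), and the Motif 1 call in the 2818 highest peaks (1.78). With genomic windows of the same GC content, DREF, Motif 1 and forkhead stayed higher at 3.74, 8.61 and 1.24, CTCF passed as higher at 1.75, TATA and GATA no longer passed (1.08 and 1.09), and no motif was lower. These genomic windows were not matched on distance to a start. Against flanking windows CTCF passed as lower with the highest peaks of replicate 2 alone (0.742) and with windows of 100 bp either side (0.819). Of all 6-mers, 295 were called as enriched. AAATAT had the lowest p (36.1% against 15.9% of windows, odds ratio 2.98), and TTAAAA and ATATTA had odds ratios of 3.05 and 3.35. Of those 295, 36 held only A and T, which is every 6-mer of that kind, and 154 held 1 G or C. Against genomic windows of the same GC content 55 were called, of which 0 held only A and T and 0 held 1 G or C. Against shuffled windows 88 were called.

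The next question was which genes carried the peaks. Of 13968 protein-coding genes, 3664 (26.2%) had a reproducible summit within 1 kb of a start. These genes shared 3084 summits, since 1 summit counts for every gene with a start that near. A peak counted for a gene can therefore lie inside or nearer to a neighbouring gene. Fisher's exact test treats genes as independent, so its intervals and p-values can be too small for lists whose members share a summit. Ribosomal protein genes had one in 77 of 92 cases (83.7%, 74.5 to 90.6), against 25.9% of other genes, an odds ratio of 14.7 (8.46 to 25.6, Fisher's exact test, adjusted p = 1.32e-29). Their highest peaks were at RpS27 (3R, summit 25247521), RpL7 (2L, summit 10201051), RpL34b (3R, summit 9401341) and RpL14 (3L, summit 8600962), all within 115 bp of a start and at ranks 108, 152, 195 and 268 of 5636. RpL10Aa and RpL21 had none. Chemosensory receptor genes (odorant, gustatory and ionotropic families), which act mainly in sensory neurons, had a peak in 5 of 179 cases (2.79%, 0.913 to 6.40; odds ratio 0.0796, 0.0327 to 0.194, exact test, adjusted p = 1.92e-16). Or88a, Gr32a, Or9a and Gr64a were among the 5, and Gr10a and Gr10b had no peak. The summits counted for these 4 genes lay 643, 768, 960 and 839 bp from the receptor starts, although all lay in promoter bases. That of Gr64a lies inside the neighbouring gene CG11594. Within 500 bp of a receptor start, 1 of 179 genes had a peak.

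The other 15 lists did not pass the test. Notch pathway genes had a peak in 11 of 21 cases (odds ratio 3.10, 1.32 to 7.30, exact test, adjusted p = 0.0627), among them gro, aph-1, numb and mam. Heat shock and stress genes had one in 10 of 19 (odds ratio 3.13, 1.27 to 7.71, exact test, adjusted p = 0.0667), with the highest at Hsp83, Hsp27, Hsc70-5 and stv. With each peak given to its nearest start at any distance, the Notch pathway list and the mesoderm and muscle list passed, each at an odds ratio of 3.21 and an adjusted exact p of 0.0413. The stress list passed with the highest peaks of replicate 2 alone, at an adjusted exact p of 0.0209, and with the 2818 highest reproducible peaks, at 0.0303. Within 500 bp of a start it had a peak in 7 of 19 cases (odds ratio 1.99, 0.785 to 5.07, adjusted exact p = 0.405). Among bHLH factor genes, 19 of 52 had a peak (36.5%, exact test, adjusted p = 0.383), the highest at gce, trh, bigmax and E(spl)m3-HLH. Proteasome genes had one in 16 of 48 cases (33.3%), with the highest at Rpn3, Rpn11, Rpn5 and Rpn13. The Rpn5 summit lies inside the neighbouring gene Hat1. All 16 were among the 32 genes left when testis and related copies are set aside by symbol, a subset chosen after seeing the data. Those copies therefore had no peak.

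Tissue lists lay near the share of all genes or had wide intervals. Endoderm and midgut genes had a peak in 6 of 24 cases (95% interval 9.77% to 46.7%), including the gut regulators fkh and cad, and the myosin genes Myo61F and Myo31DF. Genes of peptide hormones and their processing had one in 6 of 23, and the 4 highest, Pal1, amon, svr and Pal2, encode enzymes of peptide processing. The Pal1 peak, 170 bp from a start, ranked 21 of 5636 (2R, 9959704 to 9960111). Neural precursor genes had one in 6 of 24 (brat, neur, hb and grh the highest) and neuronal genes in 3 of 17 (elav, Syx1A and fne). The elav peak ranked 107. Its summit lies inside the neighbouring gene arg, and that of Syx1A lies in an intron of eIF4EHP. Glial genes had one in 4 of 10 (moody, Gs2, loco and nrv2) and mesoderm and muscle genes in 6 of 21 (sls, tin, mbc and htl the highest). Hindgut and Malpighian tubule genes had one in 2 of 10 (bowl and lin), trachea and epidermis genes in 3 of 15 (crb, Ddc and shg), and blood cell and fat body genes in 1 of 15 (ush). Germ line genes had one in 3 of 9 (gcl, vas and piwi) and salivary gland genes in 4 of 9 (pip, ogre, eyg and CrebA). The lowest adjusted exact p of these lists was 0.389, for blood cells and fat body. With so few genes per list, not passing the test does not show that a difference from other genes is absent. The summits counted for Pal2, moody, mbc and Myo31DF also lie inside other genes, namely St3, CG4313, Nup98-96 and asRNA:CR44224.

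**Figure D5:**
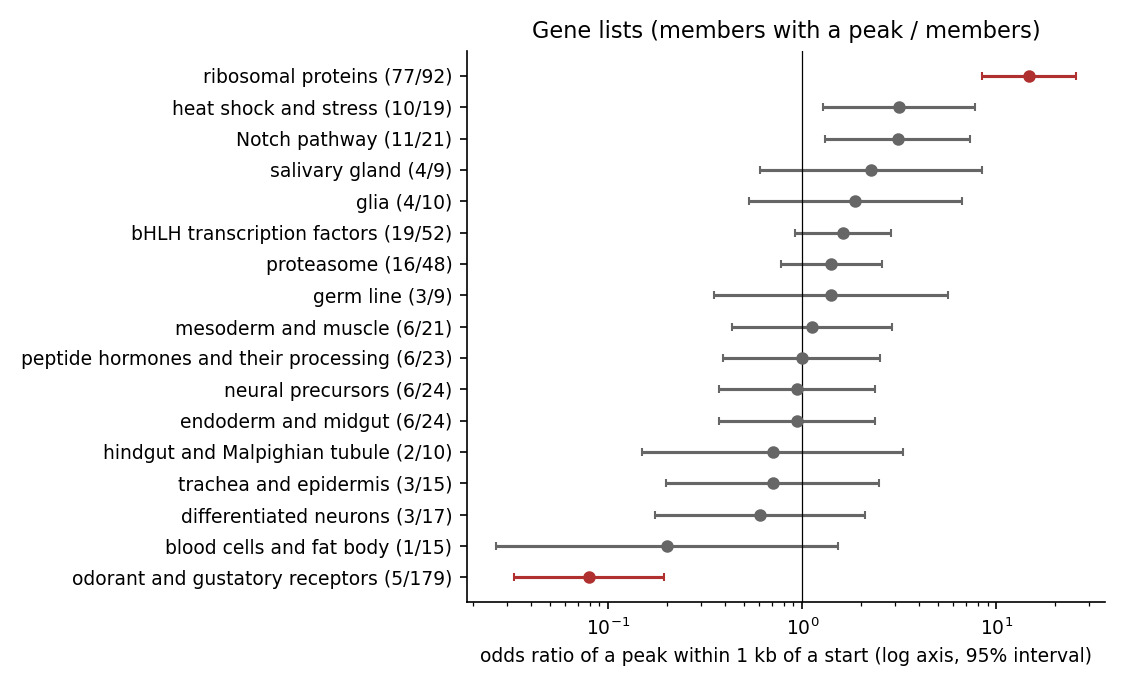
Odds ratio (log axis, 95% interval) of a reproducible summit within 1 kb of a start for each of the 17 gene lists, with members that have a peak over all members in brackets; red marks an adjusted p under 0.05. Ribosomal protein genes lie at 14.7 and chemosensory receptor genes, the list named odorant and gustatory receptors, at 0.0796.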

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

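The bases without Y, the GC-weighted shares and the GC-matched windows were chosen after seeing the data. The excess of replicate overlap over shifted lists (4.07-fold to 37.2-fold), the correlation of signal values (rho 0.730 to 0.855) and the promoter excess (2.77-fold to 5.87-fold) kept their direction and side of the threshold under each alternative run for them. Replicate 1 held 76.9% of reproducible peaks with 50% of both peaks overlapping and 94.5% with summits within 100 bp, and replicate 2 held 91.6% and 97.6%. Without Y, 1 arm differed from the rest in place of 3. With windows of 100 bp either side, 1 E-box class was higher and 8 lower, and within 500 bp of a start 6 were lower, without CAACTG (0.832). Against dinucleotide-shuffled windows 3 were higher and 1 lower, and CAAATG (1.22), CAACTG (1.22), CAAGTG (1.21), CACCTG (1.20) and CAGCTG (2.52) had odds ratios above 1, as did GAGA (1.44), CTCF (2.58), the N-box (1.04) and the initiator (1.25), while GATA (0.893) and Mef2 (0.968) fell below it. There 6 panel motifs were higher and 1 lower, and 88 6-mers were called. GAGA, CTCF and the initiator were among those that passed as higher, and GATA passed as lower (Fisher's exact test, adjusted p = 0.0222). The GAGA and GATA calls thus turned direction against this background. Against GC-matched genomic windows, 1 E-box class was higher and 0 lower, no panel motif was lower (0), and 55 6-mers were called. CAACTG (1.01), CAAGTG (1.08), CACATG (1.08), CACCTG (1.13), CACGTG (1.12), CAGCTG (1.55), CAAATG (1.01), GAGA (1.17), CTCF (1.75), Zelda (1.21), the N-box (1.13) and Grainyhead (1.14) were then above 1. Both backgrounds differ from the main one in base composition by construction, and the GC-matched windows were not matched on distance to a start. With peaks over 500 bp from a start only, 3 panel motifs were higher, as the odds ratios of DREF and Motif 1 fell to 1.64 and 2.00; the cause was not tested. With nearest starts at any distance, 4 gene lists passed in place of 2, with mesoderm and muscle and the Notch pathway each at an odds ratio of 3.21. The stress list passed with the 2818 highest peaks (3.92), and gave 3.24 to 3.83 with 1 replicate alone. Linked within 500 bp of a start, the stress list fell to 1.99 and the Notch pathway to 2.10. The cause of these list changes was not tested. Against random lists matched on gene length, 2 lists passed. The remaining changes of direction were in values that passed the test in neither setting, so their direction is not set by these data. With 1 replicate alone, ratios spanned 1 for peaks per Mb of 2R (0.959 to 1.00), CAAATG (0.989 to 1.01), AP-1 (0.798 to 1.10) and CATATG by peak height (0.925 to 1.39). So did those of the lists of peptide hormones (0.772 to 1.27), mesoderm and muscle (0.869 to 1.16), trachea and epidermis (0.695 to 1.06), germ line (0.832 to 1.39) and the proteasome (0.970 to 1.15). In the 2818 highest peaks, 3L (0.978), AP-1 (0.941), mesoderm and muscle (0.897), germ line (0.672), salivary gland (0.672) and the proteasome (0.488) fell below 1 and peptide hormones (1.13) rose above it. Without Y, 3L (0.997) and 3R (0.994) fell below 1. CATATG did with windows of 25 bp either side (0.985), and AP-1 with 100 bp (0.954), with flanks 1000 bp away (0.957) and over 500 bp from a start (0.895), where CAAATG (1.00) and Zelda (1.01) lay above 1. Linked within 500 bp of a start, glia fell to 0.854 and peptide hormones rose to 1.21. With nearest starts, endoderm and midgut (2.08), peptide hormones (1.55), neural precursors (1.46), hindgut and Malpighian tubule (1.25) and trachea and epidermis (2.55) rose above 1, and germ line (0.363) and the proteasome (0.864) fell below it. Against length-matched random lists, mesoderm and muscle had 0.814 of the mean count. The causes were not tested. Over all results and alternatives, 416 values kept their direction and side of the threshold, 24 no longer passed, 11 newly passed, 57 turned direction and 16 values or counts without a test moved. No paired analysis was possible because there is only 1 group. Depth is unknown, so its effect on the low peaks cannot be set.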

Other observations

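The family comparisons, the X and chromosome 4 comparisons, and the tests of promoter location and of proteasome genes were chosen only after the result was seen. The tests that use GC content were added after the data were examined.

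Gene families chosen by symbol differed widely in how often they held a reproducible peak within 1 kb of a start. Mitochondrial ribosomal protein genes had one in 31 of 73 cases (42.5%, 31.0 to 54.6; odds ratio 2.08, 1.31 to 3.32, Fisher's exact test, adjusted p = 0.00744 over 10 families), the highest at mRpL41, mRpS10 and mRpS23. Translation initiation and elongation factor genes (19 of 52), aminoacyl-tRNA synthetase genes (11 of 32), vacuolar ATPase genes (12 of 33) and mitochondrial complex I genes (10 of 40) did not pass. Cuticular protein genes had one in 3 of 92 cases (odds ratio 0.0941, 0.0297 to 0.297, exact test, adjusted p = 3.27e-08) and cytochrome P450 genes in 5 of 85 (odds ratio 0.175, 0.0707 to 0.431, adjusted p = 8.56e-06). The Jonah serine protease genes had none of 16 (exact test, adjusted p = 0.0202) and chorion genes none of 9 (adjusted p = 0.177). Histone genes had one in 2 of 115 (His2Av and His3.3B; odds ratio 0.0493, 0.0122 to 0.199, exact test, adjusted p = 8.30e-12). Most histone genes lie in a repeated cluster, and how reads from repeats were treated is not given in the sources used here.

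With GC-matched genomic windows as background, the 6-mer with the lowest p was ACAGTG, in 6.32% of summit windows and 2.99% of background windows (odds ratio 2.19, 1.88 to 2.55, exact test, adjusted p = 4.95e-20). ACACTG (2.01), CGATAG (2.26) and CAGTGC (1.90) followed in order of p, and GGCGCC had an odds ratio of 2.56. The background windows were not matched on distance to a start, so promoter location could add to these values.

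Peaks on the X made up 14.9% of the replicate 1 list and 17.6% of the replicate 2 list (odds ratio 0.817, 0.783 to 0.854). Among the 5000 highest peaks of each list the shares were 17.5% and 18.0% (odds ratio 0.970, 0.876 to 1.08, Fisher's exact test, p = 0.583), and among the other 25000 they were 14.4% and 17.6% (odds ratio 0.787, 0.750 to 0.826). Chromosome 4 held 74 peaks in replicate 1 and 187 in replicate 2, of which 12 and 22 were among the 5000 highest (Fisher's exact test, p = 0.121) and 62 and 165 among the others (odds ratio 0.374, 0.279 to 0.501).

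Of the 10 E-box classes, 7 were rarer at summits than 500 bp away, although Fer3 belongs to a class of E-box binding proteins. Location of the summits in promoters does not account for it, since 7 of the 10 classes were also rarer at summits over 500 bp from a start, against 6 within that distance. Base composition of the summits may account for most of it: against genomic windows of the same GC content, 0 of the 10 classes were rarer, and against dinucleotide-shuffled windows 1 was, CACGTG (0.585, 0.389 to 0.879). CAGCTG was in excess against the GC-matched windows at an odds ratio of 1.55. Those windows were not matched on distance to a start, so promoter location could add to this excess. CAGCTG was in 4.19% of summit windows within 500 bp of a start and 3.03% of the others. By height, however, it was in 2.59% of the 2818 highest peaks and 3.55% of all 5636, which include those 2818. Any E-box was in 30.4% of the 1409 highest and 36.3% of the 1409 lowest. These differences by height were not tested, high peaks also had lower GC content, and no biological explanation was tested.

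Summits had low GC content, more so in high peaks. If low GC content alone set where peaks lie, equally A/T-rich bases should carry summits at a like rate everywhere. Among bases with at most 35% GC in their window, promoters carried 384 summits per Mb and introns 91.0, a ratio of 4.22 (3.93 to 4.53), which argues against it as the whole cause. Location of the summits in promoters is not the whole cause either, because summits over 500 bp from a start differed from their flanks by −9.42 percentage points (−9.82 to −9.02). A bias of the libraries against the control that acts together with open chromatin stays open, as the control's values were not used here.

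Ribosomal protein genes held peaks far more often than other genes. Low GC content near their starts does not account for this, since within 5 bins of the lowest local GC content the pooled odds ratio was 15.4 (8.70 to 27.2). Proteasome genes without related copies, another widely expressed set, held a peak in 16 of 32 cases (50%). The odds ratio of ribosomal protein genes against these proteasome genes was 5.13 (2.12 to 12.5), which argues against a like rate at promoters of any widely expressed gene. The ribosomal list was not trimmed of related copies and kept all 92 genes. The 50% was above the 26.2% of all protein-coding genes, a difference that was not tested. Wide expression as a part of the cause thus stays open. Very high transcription or open chromatin that is precipitated whatever the tagged protein could still give this pattern, and precipitations of other tagged proteins were not analysed here. No biological explanation was tested, as the design has 1 group.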
